A study of Mus musculus with 4 samples.

How the data were processed

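Poly(A)-selected RNA from pancreatic tissue lying beside Panc02 tumours (Panc02 is a mouse pancreatic ductal adenocarcinoma line) was sequenced in 4 libraries from mice, 2 from wild-type (WT) animals and 2 from animals with a conditional knockout of CRFR1 (CRFR1-KO). Per the labels' protocols, mRNA was captured on oligo(dT) beads, fragmented, reverse-transcribed and built into libraries whose second strand was marked with dUTP and removed. The deposited table held a whole-number count per Ensembl gene and library, without normalization. Per the submitters' processing notes, FastQC, DESeq2 and edgeR were used, with no version or role attached. The aligner, the counting program, its strand setting, the annotation and the genome build behind the counts are not given in the sources used here. Each column was tied to its library by the library name in the labels.

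The table listed 55401 gene identifiers, of which 55141 had a symbol in GENCODE M21 and 260 did not. No entry of the table lacked a gene, and no per-sample column was left unmapped. Total counts were 69960284 in WT 1, 71203640 in WT 2, 70074733 in CRFR1-KO 1 and 63495457 in CRFR1-KO 2. A floor of 3 counts corresponded to between 0.0363 and 0.048 CPM (counts-per-million), and folds against a group at 0 were computed against the mean of its libraries' floors. In every library the counts 4, 8 and 12 were more frequent than their neighbours. In WT 1, for example, 913 genes had a count of 4, against 349 with 3 and 242 with 5. What a single deposited count stands for in read pairs is therefore not settled, so floors and intervals refer to deposited counts and to counting error only. Some genes share exon bases with another gene identifier on the same strand: 3330 identifiers in 1371 groups did so in GENCODE M21, and their counts depend on how the counting program divided reads between them.

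Genes were tested in R 4.3.3 with edgeR 4.0.16 (trimmed mean of M values scaling, filterByExpr with default settings, quasi-likelihood F test, two-sided, group as the sole term), and p-values were adjusted by the Benjamini-Hochberg method over the 15131 genes that passed the filter, at a threshold of 0.05. The standard error (SE) of a log2 fold change was derived from its F statistic. Levels are CPM on the scaled library sizes, given as mean ± SD over the 2 libraries of a group. Fold changes are CRFR1-KO over WT. The prior degrees of freedom were 5.1 and the biological coefficient of variation was 0.3. A rank or permutation test of a single value with 2 libraries against 2 cannot go below a two-sided exact p of 0.333, so none was used. Camera in limma 3.58.1 compared 39 gene lists (pathways, cell types and technical classes) with all other tested genes, with a preset inter-gene correlation of 0.01, for the 36 lists with at least 5 tested members. The same lists were tested with an estimated correlation and with fry.

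The lists, tests, scalings, filters and the rule for named genes were chosen before the data were examined. The rule took genes past the adjusted threshold with a named-gene symbol (not a predicted-gene or Rik symbol), a mean of at least 5 CPM over the 4 libraries and both libraries of one group above both of the other. It took up to 12 per direction, filled to 6 per direction by the smallest unadjusted p, with the fill given as values. It always took Crhr1, Crh, Crhr2, Ucn, Sphk1, Sphk2, Mapk3, Mapk14, Cpa3, Cma1, Mcpt4, Tpsb2 and Kit, and up to 4 members with the smallest p from each list past its threshold and each list tied to the series title. Any other gene named was chosen after its values were seen. Some genes the rule took are not reported here.

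The alternatives were DESeq2 size factors, upper quartile scaling, library totals, leaving out the acinar list, other filters on low counts, the DESeq2 1.42.0 Wald test, limma-voom, robust estimation, a test against a fold of 1.5, a threshold of 0.1, a replicate block and leaving out each library in turn. Summing exon-sharing gene models, and dividing every count by 4 with rounding, were added after seeing the data. The edgeR test was tested on simulated data for CRFR1-KO against WT, with 5 simulations of 15131 genes and 200 changed genes each. It called 32.9% of genes changed 2-fold, 74.2% of those changed 4-fold and 0.0419% of unchanged genes. Simulated genes took their variability from its trend over expression, with none of their own and with no library set apart. These rates may therefore be too favourable for the real libraries. Simulated lists of 20 genes lowered 1.5-fold had an unadjusted camera p under 0.05 in 5 of 5 simulations, and unchanged lists in 0 of 5. Both held with either correlation. Simulated genes varied independently of each other, whereas the extracellular matrix list had an estimated correlation of 0.465. The simulations therefore cannot tell how often camera calls correlated lists wrongly or misses them. Gene positions are those of GENCODE M21 on GRCm38 and were not used in any test.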

Results

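The series asks, by its title, whether CRFR1 in mast cells contributes to pancreatic cancer pain through MAPK and SPHK1 signalling. CRFR1, the product of Crhr1, is a receptor for corticotropin-releasing factor (CRF), a stress peptide. Gene expression was measured by RNA-seq in tissue beside Panc02 pancreatic tumours of WT and CRFR1-KO mice, with 2 libraries per genotype and between 63495457 and 71203640 counts per library. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical. The tissue was dominated by exocrine pancreas. Genes of the acinar list, mostly digestive enzymes, held 65.9% of the counts in WT 1, 65.9% in WT 2, 67.8% in CRFR1-KO 1 and 68.5% in CRFR1-KO 2, which left between 20020480 and 24271169 counts per library for all other genes. Of these, between 9693786 and 13059398 counts belonged to Amy2a3, Amy2a4 and 2210010C04Rik, 3 of the 10 most abundant genes that the list lacks. Chymotrypsinogen Ctrb1, the near-identical amylase genes Amy2a2 to Amy2a5, elastases Cela1 and Cela2a, lipase Pnlip and carboxypeptidase Cpb1 were among the 10 most abundant genes, which together took 53.0% to 58.1% of each library. Reads shared between the amylase copies make the level of any single copy uncertain. Pearson's r of log2(CPM + 0.5) across genes lay between 0.968 and 0.980 for every pair of libraries, and genes are not independent replicates. No pair was a duplicate, with a chi-square per degree of freedom of at least 43.6.

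Crhr1 (ENSMUSG00000018634; chromosome 11, 104132855 to 104175523, GRCm38 in GENCODE M21) had a count of 0 in all 4 libraries. At a floor of 3 counts this allows up to 0.0363 CPM in WT 1 and 0.048 CPM in CRFR1-KO 1, so neither the receptor nor its loss was detectable at this depth and the genotype labels could not be checked from it. The CRF ligand gene Crh, the related ligand gene Ucn and the CRF-binding protein gene Crhbp were likewise at 0 in all 4 libraries, and Crhr2, the second CRF receptor, had 0 and 4 counts in WT and 0 and 6 in CRFR1-KO. Of the 5 tested members of the CRF list, 3 were higher and 2 lower. Fkbp5, a glucocorticoid-induced gene, stood at 7.77 ± 5.33 CPM in WT and 3.31 ± 0.90 CPM in CRFR1-KO (SD, n = 2 libraries each), and did not pass the edgeR test (log2 fold change -1.23, SE 0.47). It did without WT 1 (log2 fold change -1.80, edgeR adjusted p = 0.0481). Ucn3, a ligand gene of the same family, had 4 and 33 counts in WT and 33 and 69 in CRFR1-KO (log2 fold change 1.53, SE 1.03) and did not pass either. With all 4 libraries the list was not called (camera adjusted p = 0.971), at a median of 0.10 over the 5 tested genes. The median was -0.33 over 6 without WT 1 and -0.359 over 6 without CRFR1-KO 1, both with the list's test turned to lower. Leaving out a library leaves its group a lone library, so only the list's median and direction are given for these fits. The genes passing the filter thus differed between these fits, and the shift is not that of one fixed list.

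Mast cell transcripts were scarce in both genotypes. Of the 21 mast cell genes listed, 12 had a count of 0 in every library, among them the protease genes Cma1, Mcpt4 and Tpsb2. Cpa3, encoding mast cell carboxypeptidase, had 39 and 8 counts in WT and 33 and 4 in CRFR1-KO. Kit, the stem cell factor receptor, stood at 12.5 ± 1.7 CPM in WT and 12.3 ± 2.3 CPM in CRFR1-KO (SD, n = 2 libraries each; log2 fold change -0.02, SE 0.20), and is also expressed by other cells. Of 7 tested members, 3 were higher and 4 lower. Hpgds, encoding a prostaglandin D synthase that macrophages also express, was the sole member past the threshold adjusted over the list alone (log2 fold change -1.66, SE 0.37, edgeR p 0.0196 adjusted over the list alone and 0.682 over all genes). Over all genes 0 members passed in edgeR (1 at an unadjusted p under 0.05), DESeq2 or limma-voom. The Hpgds call was lost without WT 1 and without CRFR1-KO 1. The list was not called (camera adjusted p = 0.61), with a median log2 fold change of -0.02, which became 0.20 without WT 2 and 0.27 without CRFR1-KO 2.

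Sphk1, which encodes the sphingosine kinase named in the title (ENSMUSG00000061878; chromosome 11, 116530925 to 116536674, GRCm38), was measured lower in both CRFR1-KO libraries than in either WT library. Its counts were 336 and 374 in WT and 124 and 146 in CRFR1-KO, or 4.89 ± 1.17 CPM against 2.11 ± 0.17 CPM (SD, n = 2 libraries each). The log2 fold change was -1.21 with an SE of 0.27. It did not pass after adjustment by edgeR over all genes (adjusted p = 0.682) or adjusted over the list alone (0.0831). The log2 fold change of Sphk1 was -1.437 without WT 1 and -0.9428 without WT 2. Sphk2, the other sphingosine kinase, differed by less than the spread between libraries, at 9.07 ± 0.20 CPM in WT and 9.20 ± 0.32 CPM in CRFR1-KO (log2 fold change 0.02, SE 0.17, and -0.11 when scaled on library totals). Of the 29 tested members of the sphingosine-1-phosphate list, 16 were higher and 13 lower. The ceramidase genes Acer3 and Acer2 had log2 fold changes of -0.71 and -0.71, and the receptor gene S1pr3 of 0.78, none past the adjusted threshold in edgeR. The list was not called (camera adjusted p = 0.971; direction lower, median 0.05, mean -0.04). Its median was -0.0283 without WT 1 and -0.015 without CRFR1-KO 1.

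Genes of the MAPK cascade lay close together in the 2 genotypes. Mapk3 (ERK1) stood at 16.5 ± 0.1 CPM in WT and 15.3 ± 1.1 CPM in CRFR1-KO, and Mapk14 (p38 alpha) at 17.4 ± 0.5 and 16.9 ± 2.5 CPM (SD, n = 2 libraries each). Their log2 fold changes were -0.10 (SE 0.16) and -0.05 (SE 0.18), each below its SE. Of 38 tested cascade components, 14 were higher and 24 lower (camera adjusted p = 0.709), with Map3k1 at -0.37 and Nras at -0.42 on the log2 scale. The cascade's median went from -0.102 to 0.0207 without WT 2. Transcriptional targets of the pathway leaned lower. In the MAPK output list, 15 of 17 genes were lower, with Etv5 at -1.21 and the cyclin gene Ccnd1 at -0.44 (camera adjusted p = 0.136). In the immediate early list 14 of 18 were lower, with Nr4a1 at -0.62 and Junb at -0.90 (camera adjusted p = 0.0893). Junb was not separated by genotype, at 4.52 CPM in WT 1 and 1.93 CPM in WT 2 against 1.12 and 2.34 CPM in CRFR1-KO. With all 4 libraries neither list passed the threshold. Of their members 0 passed in edgeR, adjusted over the list alone or over all genes, with 1 and 0 members at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 over all genes. With an estimated correlation, camera gave the MAPK output and immediate early lists p of 0.18 and 0.15 (adjusted p = 0.604 for both). Their medians were -0.231 and -0.303 without WT 2, and -0.255 and -0.392 without CRFR1-KO 2. Such fits leave a group a lone library, so whether the lists passed in them is not given here. Without WT 1 the lean was weaker. The median of the MAPK output list then went from -0.285 to -0.11, with 10 of 17 genes lower, and that of the immediate early list from -0.276 to -0.153, with 13 of 19 lower. RNA levels do not measure kinase activity.

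The list of pain and neurotrophic mediators also leaned lower, with 19 of 25 tested genes below WT and a median log2 fold change of -0.33. Gfra1, a receptor for the neurotrophic factor GDNF, stood at 5.01 ± 0.24 CPM in WT and 2.46 ± 0.57 CPM in CRFR1-KO (SD, n = 2 libraries each; log2 fold change -1.02, SE 0.26). Ptges, a prostaglandin E synthase gene, was at -1.16, the endothelin receptor gene Ednra at -1.13 and the bradykinin receptor gene Bdkrb2 at 1.02 on the log2 scale. Of the list's members, 0 passed in edgeR adjusted over the list alone and 0 over all genes (2 lower at an unadjusted p under 0.05), and DESeq2 and limma-voom called 0. The list missed the threshold (camera adjusted p = 0.0533; 0.814 with an estimated correlation). With the preset correlation camera called it lower when exon-sharing models were summed (adjusted p = 0.044), without the acinar list (0.0383), with counts divided by 4 (0.0224) and without WT 2 (0.0304). Without WT 1 the median was -0.0979, with 18 of 29 genes lower.

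Across the transcriptome, 4 of 15131 tested gene models passed the edgeR threshold, 2 higher and 2 lower in CRFR1-KO. Zc3h11a, encoding a zinc finger protein (ENSMUSG00000102976; chromosome 1, 133619862 to 133661380, GRCm38), had 127 and 48 counts in WT and 1166 and 1608 in CRFR1-KO (log2 fold change 4.23, SE 0.36, edgeR adjusted p = 0.0308). The other 3 were named after their values were seen. A Sept2 model (ENSMUSG00000116048) had 747 and 442 counts in WT and 0 in both CRFR1-KO libraries. Gm45062 (ENSMUSG00000107705) had 516 and 383 in WT and 0 in both CRFR1-KO libraries (edgeR adjusted p = 0.00848 for both). Against a floor of 3 deposited counts they were at least 168-fold and 129-fold lower. What a deposited count stands for is not settled, and a higher floor would give smaller folds. The long noncoding RNA 1810007D17Rik, which lies 22745 bp upstream of Pnlip (ENSMUSG00000100001; chromosome 19, 58606329 to 58629753, GRCm38), had 89 and 93 counts in WT and 506 and 720 in CRFR1-KO (log2 fold change 2.94, SE 0.27, edgeR adjusted p = 0.0407).

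The Sept2, Zc3h11a and Gm45062 models share exons with other gene models, and several of those partner models ran the opposite way. A second Sept2 model (ENSMUSG00000026276) had 1045 and 1139 counts in WT and 1436 and 1385 in CRFR1-KO, and Glcci1, which overlaps Gm45062, had 58 and 12 in WT and 446 and 440 in CRFR1-KO. A second Zc3h11a model (ENSMUSG00000116275) had 1780 counts in WT 2 and 0 in the other 3 libraries. Summed over the models, Sept2 had 1792 and 1581 counts in WT and 1436 and 1385 in CRFR1-KO (log2 fold change -0.05, SE 0.16). The Zc3h11a group stood at -0.12 (SE 0.16) and the Gm45062, Glcci1 and Umad1 group at 0.21 (SE 0.16). After summing, 0 of 14749 genes passed in edgeR, with 701 at an unadjusted p under 0.05, and 1810007D17Rik, which shares exons with no other model, missed the threshold (adjusted p = 0.126). Its log2 fold change was 2.94 (SE 0.27) before and after, and the call ended because the models that had ranked above it in the adjustment were gone. On the models as deposited, the DESeq2 Wald test called 59 (13 higher, 46 lower) and limma-voom 0. Of those 59, 37 (6 higher, 31 lower) share exons with no other model.

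**Figure D1:**
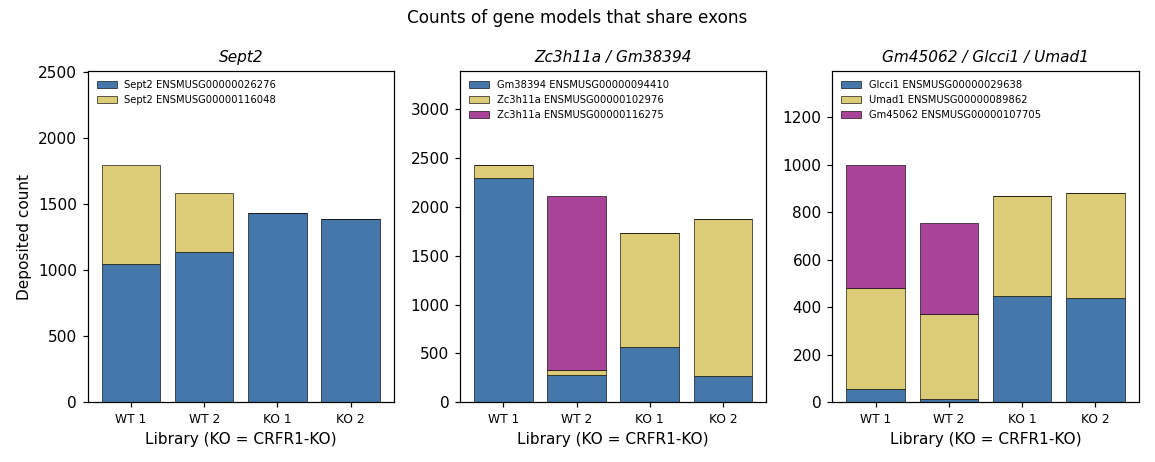
Deposited counts of gene models that share exons, stacked by model for each of the 4 libraries, for Sept2, for Zc3h11a with Gm38394, and for Gm45062 with Glcci1 and Umad1. Single models switch between the genotypes or libraries, while the stacked total stays between 1385 and 1792 for Sept2, between 1734 and 2422 for Zc3h11a and between 753 and 996 for Gm45062.

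Leaving out WT 1 gave 40 calls in edgeR and leaving out WT 2 gave 69, against 2 without CRFR1-KO 1 and 0 without CRFR1-KO 2. At an unadjusted p under 0.05 there were 735 genes (258 higher, 477 lower), against 757 from chance alone, and the libraries of the 2 genotypes were fully separated for 5070 genes, or 33.5%, against 33.3% by chance.

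Genes that did not pass the edgeR adjustment were taken by smallest p among those with a named-gene symbol, a mean of at least 5 CPM and both libraries of one genotype above both of the other. Among those measured lower, Mmp2, a gelatinase gene, stood at 18.3 ± 0.5 CPM in WT and 7.15 ± 0.59 CPM in CRFR1-KO (log2 fold change -1.35, SE 0.17, edgeR adjusted p = 0.181), and Eln, encoding elastin, at 18.6 ± 6.5 and 5.20 ± 0.0064 CPM (log2 fold change -1.84, SE 0.26, edgeR adjusted p = 0.251; SD, n = 2 libraries each). DESeq2 called both lower (adjusted p = 1.62e-05 and 2.67e-07). Without WT 1, Mmp2 and Eln stood at -1.32 and -2.154 on the log2 scale, and without WT 2 at -1.377 and -1.426. Gadd45g, a growth arrest gene, was at -1.54, the ribosomal protein gene copy Rps27rt at -1.36, the glutamine synthetase gene Glul at -1.27 and Igfbp4, encoding an insulin-like growth factor binding protein, at -1.15 on the log2 scale. DESeq2 called these 4 lower as well (adjusted p = 0.00208, 0.000485, 0.00466 and 0.00278, in that order). On the higher side stood Rnpc3 (108 ± 19 against 328 ± 126 CPM, log2 fold change 1.61), Snrpn (0.74), the antisense RNA Galnt6os (0.68), Apol7a (0.74) and the choline dehydrogenase gene Chdh (0.61), none past the edgeR adjustment. Of these, DESeq2 called Rnpc3 alone (adjusted p = 2.07e-07). Rnpc3 and Snrpn share exons with other models, and their summed log2 fold changes were 0.09 and 0.46. Glul, and below Spp1, Ctrc and Pdgfra, also share exons with another model and kept their direction when models were summed, with Ctrc at 0.20 on the log2 scale in place of 0.53.

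**Figure D2:**
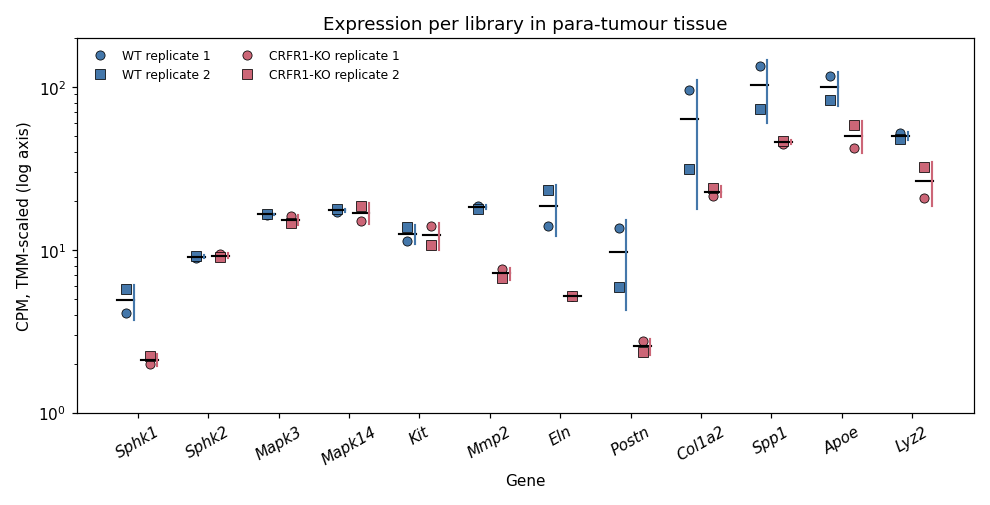
Expression in CPM, on a log axis, of Sphk1, Sphk2, Mapk3, Mapk14, Kit, Mmp2, Eln, Postn, Col1a2, Spp1, Apoe and Lyz2 in each library (points), with the group mean (black bar) and ± SD (coloured line, n = 2 libraries each). Sphk1, Mmp2, Eln and Postn lie lower in both CRFR1-KO libraries than in either WT library, Kit overlaps between genotypes, and Col1a2 has its highest value, 96.1 CPM, in WT 1.

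Of the 36 gene lists tested, camera called 10 with its preset correlation, 2 higher and 8 lower in CRFR1-KO, and 0 with an estimated correlation (smallest adjusted p = 0.604; 1 list at an unadjusted p under 0.05). Fry, which asks whether a list's genes move on balance in one direction, called 0 (smallest adjusted p = 0.631). WT 1 stood apart from the other 3 libraries: of 2388 abundant gene models, 12 were over 4-fold above the median of the others in WT 1, against 0 or 1 in the other libraries, and the extracellular matrix list lay a median of 0.861 log2 units higher in WT 1 than in WT 2.

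Extracellular matrix genes were lower in CRFR1-KO in nearly every case, at 33 of 34 tested members with a median log2 fold change of -0.95. Postn, encoding the matricellular protein periostin, stood at 9.74 ± 5.48 CPM in WT and 2.55 ± 0.28 CPM in CRFR1-KO, the collagen crosslinking enzyme gene Lox at 5.05 ± 1.59 and 1.68 ± 0.65 CPM, and its relative Loxl1 at 6.59 ± 1.26 and 3.54 ± 0.26 CPM (SD, n = 2 libraries each). The list fell (camera adjusted p = 4.91e-20), a call lost with an estimated correlation (p = 0.112, adjusted p = 0.604). In edgeR 12 members were lower adjusted over the list alone and 0 passed over all genes (17 lower at an unadjusted p under 0.05). Over all genes DESeq2 called 2, Mmp2 and Postn (adjusted p = 1.62e-05 and 0.000562), and limma-voom 0. Without WT 1 the list's median was -0.31, with 25 of 33 members lower and 2 past the threshold adjusted over the list alone, and camera still called it (adjusted p = 2.49e-05). That count of 12 became 23 without WT 2, 0 without CRFR1-KO 1 and 1 without CRFR1-KO 2.

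Fibroblast and macrophage markers were lower as well. In the fibroblast list, which shares 4 genes with the matrix list, 21 of 23 members were lower (median -0.58), among them Mfap5, a microfibril component (4.12 ± 0.75 against 1.56 ± 0.0043 CPM), the receptor gene Pdgfra (10.2 ± 2.3 against 6.002 ± 0.931 CPM) and Lum, encoding lumican (11.95 ± 5.86 against 5.42 ± 1.06 CPM). The list fell (camera adjusted p = 5.31e-10; p = 0.0406, adjusted p = 0.604, with an estimated correlation). In edgeR 1 member, Mfap5, passed adjusted over the list alone, against 5 without WT 1, 6 without WT 2 and 0 without either CRFR1-KO library. In the macrophage list 22 of 26 members were lower (median -0.83), among them Apoe, which carries lipids (99.9 ± 23.2 against 50.3 ± 11.2 CPM), the lysozyme gene Lyz2 (49.8 ± 2.9 against 26.5 ± 7.9 CPM) and the complement genes C1qb and C1qc (log2 fold changes -1.12 and -0.90; SD, n = 2 libraries each). The list fell (camera adjusted p = 1.21e-09; p = 0.0821, adjusted p = 0.604, with an estimated correlation), with 0 members past the edgeR threshold adjusted over the list alone (7 lower at an unadjusted p under 0.05). Over all genes DESeq2 called 3 members lower, Apoe (adjusted p = 0.00647), Lyz2 (0.0325) and Gpnmb (0.0414), and limma-voom 0. Without WT 1 the list's median was -0.50 and the call stood, and 1, 13 and 4 members passed that way without WT 1, WT 2 and CRFR1-KO 2.

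Genes of acinar injury and ductal epithelium were mostly lower in CRFR1-KO, and some of them, such as Reg3a and Lcn2, had far more counts in WT 1 than in any other library. In the list of pancreatitis and acinar injury genes, 14 of 17 members were lower (median -0.95), led by Spp1, encoding osteopontin (103 ± 43 against 45.8 ± 1.4 CPM), and the regenerating protein genes Reg3a (308 ± 419 against 12.7 ± 6.1 CPM) and Reg3d (333 ± 127 against 172 ± 43 CPM; SD, n = 2 libraries each). Reg3a had 49979 counts in WT 1 and 760 in WT 2, against 1062 and 547 in CRFR1-KO. Mmp7, encoding matrilysin, had 45 and 30 counts in WT and 4 and 0 in CRFR1-KO. The list fell (camera adjusted p = 3.77e-05; p = 0.184 with an estimated correlation), but without WT 1 its median was -0.01 and it was not called (adjusted p = 0.857). Without WT 2 the list's median was -1.29. With all 4 libraries, 0 members passed in edgeR adjusted over the list alone (8 lower at an unadjusted p under 0.05). Over all genes DESeq2 called 2 lower, Spp1 and Reg3d (adjusted p = 0.00208 and 0.0493), and limma-voom 0. The ductal list, which shares 6 genes with it, had 14 of 20 members lower, among them the siderophore-binding protein gene Lcn2 (1502 and 84 counts in WT, 31 and 16 in CRFR1-KO), the keratin gene Krt20 (log2 fold change -4.79) and the ductal transcription factor gene Sox9 (-0.79). It fell too (median -0.21, camera adjusted p = 0.00633; p = 0.157 with an estimated correlation). Spp1 and Lcn2 passed in edgeR adjusted over the list alone (6 members without WT 2 and 0 without any other library). The list's call was lost without WT 1 (median -0.09, adjusted p = 0.218) and without CRFR1-KO 2 (median -0.28, adjusted p = 0.124).

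Cytokine genes, lipid mediator genes and adipocyte markers made up the remaining lower lists. Of 9 tested cytokine genes 8 were lower (median -0.88), among them the alarmin Il33 (2.64 ± 1.70 against 0.59 ± 0.33 CPM, SD, n = 2 libraries each) and the chemokines Ccl8, Ccl6 and Ccl9 (log2 fold changes -2.92, -0.88 and -0.61). The Ccl8 value rested largely on WT 1, with 350 counts there and 45 in WT 2, against 5 and 37 in CRFR1-KO. A further 27 genes of the cytokine list were too low to test. The list fell (camera adjusted p = 0.000547; p = 0.0555 with an estimated correlation), a call lost without WT 1 (adjusted p = 0.124) although the median was then -1.08 over 11 genes. Without CRFR1-KO 1 the median was -1.73 over 16 genes. In the arachidonic acid list 9 of 13 members were lower (median -0.59). Hpgds passed the edgeR threshold adjusted over the list alone, but 0 members did with any 1 of the 4 libraries left out. Alox5ap, needed for leukotriene synthesis, stood at -0.83 and the prostacyclin synthase gene Ptgis at -0.80 on the log2 scale. The list fell (camera adjusted p = 0.0396; p = 0.306 with an estimated correlation), but its median was 0.02 without WT 1 (adjusted p = 0.495), and the call was also lost without CRFR1-KO 1 (median -0.328, adjusted p = 0.163), on library totals (0.0763) and with no filter on low counts (0.0617). In the adipocyte list 8 of 10 members were lower (median -0.34), among them the fatty acid transporter gene Cd36 (11.3 ± 0.8 against 6.52 ± 1.46 CPM), the lipid droplet gene Plin4 (64 and 371 counts in WT, 21 and 33 in CRFR1-KO), Dgat2 (-1.80, resting on WT 2, with 0.40 CPM in WT 1 and 2.38 CPM in WT 2 against 0.34 and 0.46 CPM in CRFR1-KO) and Pparg (-0.70). It fell (camera adjusted p = 0.00984; p = 0.0961 with an estimated correlation), though not without WT 2 (median -0.139, adjusted p = 0.337). Its median was -0.87 without WT 1 and -0.587 without CRFR1-KO 1.

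Acinar and islet genes were the lists called higher in CRFR1-KO. Of 34 acinar genes 26 were higher (median 0.20), among them the chymotrypsin gene Ctrc (140 ± 15 against 202 ± 5 CPM), the trypsinogen gene Try5 (11123 ± 1442 against 15854 ± 409 CPM), and the acinar transcription factor genes Bhlha15 and Ptf1a (log2 fold changes 0.40 and 0.44). The list rose (camera adjusted p = 0.00861; p = 0.385 with an estimated correlation), though not without WT 1 (median 0.04, adjusted p = 0.461) or without CRFR1-KO 1 (median 0.128, adjusted p = 0.102). Without WT 2 its median was 0.373. Of 26 islet genes 20 were higher (median 0.64), among them the prohormone convertase gene Pcsk1 (2.21 ± 0.87 against 4.46 ± 0.43 CPM), the glucose transporter gene Slc2a2 (0.93 ± 0.82 against 3.04 ± 0.93 CPM; SD, n = 2 libraries each) and G6pc2 (log2 fold change 1.51). The list rose (camera adjusted p = 2.3e-05; p = 0.306 with an estimated correlation), but the insulin gene Ins2 had 1570 counts in WT 1 against 7602 in WT 2, 7505 in CRFR1-KO 1 and 10509 in CRFR1-KO 2, and without WT 1 the median was -0.00224 with no call (adjusted p = 0.482). Without WT 2 and without CRFR1-KO 2 it was 2.68 and 0.353. In neither list did any member pass in edgeR adjusted over the list alone (1 acinar and 3 islet genes at an unadjusted p under 0.05) or in DESeq2 or limma-voom over all genes, although 20 islet genes did without WT 2 and 1 without WT 1.

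**Figure D3:**
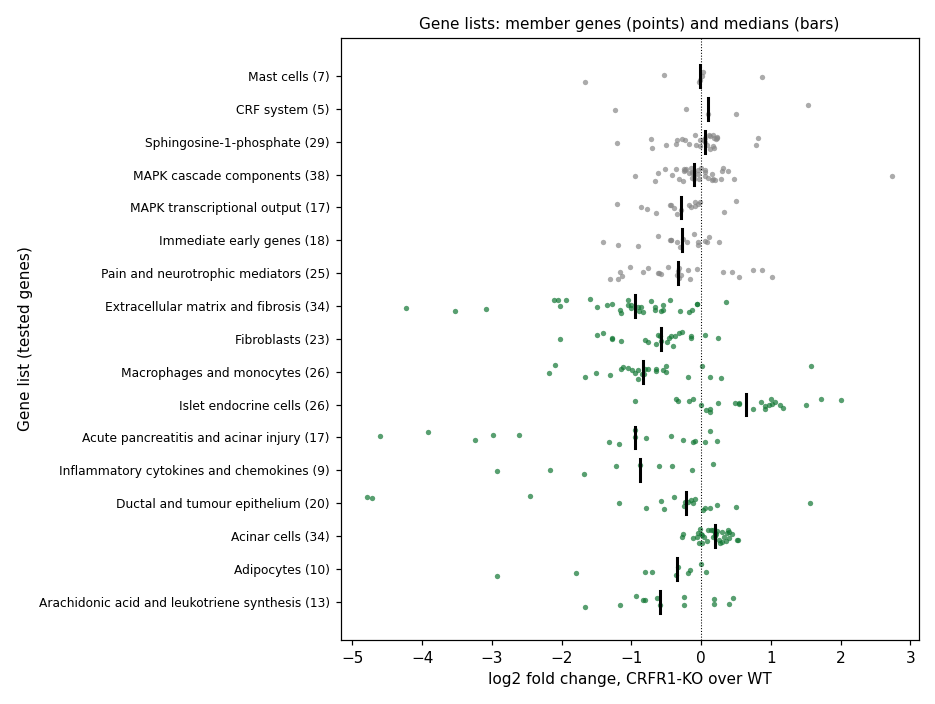
Log2 fold change, CRFR1-KO over WT, of the tested members (points) and their median (bar) in 17 gene lists, grey for the 7 lists tied to the series title and green for the 10 lists camera called with its preset correlation. The extracellular matrix list lies lower, at a median of -0.95, the islet list higher, at 0.64, and the mast cell list at -0.02.

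Of the remaining 19 lists camera called none with its preset correlation. Endothelial markers were balanced, with 11 of 23 higher and 12 lower (median -0.03, camera adjusted p = 0.971). Proliferation genes had a median of -0.94 with a wide spread (camera adjusted p = 0.479), since Mki67 had 410 and 7 counts in WT and 56 and 116 in CRFR1-KO. The interferon list (camera adjusted p = 0.334), the unfolded protein response (0.971), glycolysis and hypoxia (0.971) and oxidative phosphorylation (0.971) were not called, nor were smooth muscle and pericytes (0.136), mesothelial cells (0.275), dendritic cells (0.334), B and plasma cells (0.61), and Schwann cells and neurons (0.709). Skeletal muscle (0.971), intestinal epithelium (0.824) and erythroid cells (0.829) were not called either, and neither were mitochondrially encoded genes (0.219), ribosomal proteins (0.971) or replication-dependent histones (0.61). Neutrophil, hepatocyte and sex-linked lists had fewer than 5 tested members, and Y-linked genes such as Ddx3y (1221 and 886 counts in WT, 921 and 779 in CRFR1-KO) were expressed in all 4 libraries.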

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

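Summing exon-sharing models and dividing counts by 4 were chosen after the result was seen; all other settings here were planned. The 4 edgeR calls were kept under DESeq2 size factors, upper quartile scaling, library totals (which shifted the median of all genes to -0.133), without the acinar list, with robust estimation, with a filter of at least 1 CPM in 2 libraries, at a threshold of 0.1, with no filter (6 calls) and with counts divided by 4 (6 calls), and 3 of them in a test against a fold of 1.5. The count was 59 with the DESeq2 Wald test, 0 with limma-voom, 7 with the replicate block and 0 after summing exon-sharing models, and ranged from 0 to 69 on leaving out 1 library. The replicate numbers did not pair the libraries (correlation of same-numbered deviations -0.0747), and the block ended the call of 1 list, arachidonic acid (adjusted p = 0.0615), while the direction of the CRF list's test, though not its median, turned under it (median 0.091) and under fry (0.103). Called lists numbered 10, against 0 with an estimated correlation, 0 with fry, 9 on library totals, 9 with no filter, 9 with the replicate block, 12 after summing and 12 with counts divided by 4, and 8 to 20 on leaving out 1 library. Sphk1 stayed between -1.437 and -0.9428 under every setting, with an adjusted p from 0.146 to 1. Summing turned the log2 fold change of Zc3h11a to -0.1237, of Gm45062 to 0.2132 and of the second Sept2 model to -0.05389, since the partner models' counts were added, and library totals turned Sphk2 to -0.1078. On leaving out 1 library the direction turned for Sphk2 (-0.01495 to 0.06444), Mapk14 (-0.1985 to 0.1021), Cpa3 (-2.253 to 1.256), Kit (-0.2259 to 0.1664), Ptgis (-1.334 to 0.03469), Reg3a (-5.572 to 0.1273), Il1rl1 (-1.177 to 0.6023), Tsc22d3 (-0.6369 to 0.3897) and Ucn2 (-0.5642 to 1.313), and for the median or the direction of the islet list (-0.00224 to 2.68), the mast cell list (-0.267 to 0.266), the CRF list (-0.359 to 0.39), the sphingosine-1-phosphate list (-0.0283 to 0.125) and the MAPK cascade list (-0.0986 to 0.0207); the cause was not tested. With a library left out, its group's lone library is assumed to vary like the pair of the other group. Of the values for single named genes under the alternatives, 1302 kept direction and side of the threshold, 35 newly passed, 13 no longer passed and 17 reversed, and for single lists 169, 7, 32 and 11. Depth limits Crhr1, Crh, Ucn and most mast cell genes, which stayed at or under the floor.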

Other observations

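Of the tests below, the tests of library scaling and of exon sharing across all abundant models were set before their result was seen; the tests on the summed groups, on abundant models outside the called groups, on 1810007D17Rik, on WT 1, on endothelial genes, on other splits and on Sphk1 in the WT libraries were chosen only after the result was seen.

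Antigen presentation genes leaned higher. Of 9 tested genes of the MHC class II list 8 were higher in CRFR1-KO (median log2 fold change 0.53), among them H2-Ab1 (3.48 ± 0.02 against 5.91 ± 1.28 CPM), H2-Eb1 (3.71 ± 0.32 against 5.63 ± 0.49 CPM) and the invariant chain gene Cd74 (12.4 ± 3.0 against 18.5 ± 0.7 CPM; SD, n = 2 libraries each). The list just missed the threshold (camera adjusted p = 0.0526; p = 0.129, adjusted p = 0.604, with an estimated correlation), and its difference from the macrophage list was not tested. Ctss, a lysosomal protease gene in the same list, was the one member lower (log2 fold change -0.86) and the one past the edgeR threshold adjusted over the list alone (0.0242). T and NK cell genes leaned lower (9 of 13, camera adjusted p = 0.0558). Prox1, a transcription factor gene of the endothelial list, stood at 4.35 ± 0.52 CPM in WT and 1.63 ± 0.36 CPM in CRFR1-KO (edgeR p 0.0362 adjusted over the endothelial list alone and 0.586 over all genes). The mucin gene Muc2 had 0 counts in both WT libraries and 23 and 20 in CRFR1-KO (edgeR p 0.0294 adjusted over the intestinal list alone).

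WT 1 carried several regenerating protein genes far above the other libraries, at 50-fold over their median for Reg3a, 42.3-fold for Reg3b, 17.8-fold for Reg3g and 16.7-fold for Reg2. Lcn2 (18.7-fold), Krt20 (13.9-fold) and Col1a1 (6.33-fold) went with them, while Gcg and Ins2 were lowest there (676 and 1570 counts, against at least 2273 and 7505 elsewhere). Reg1 was not highest in WT 1 (6348.7 CPM, against 7716.5 in WT 2, 6427.1 in CRFR1-KO 1 and 5365 in CRFR1-KO 2). Reg3d was less far above (422 CPM, against 243, 202 and 142 in the same order). In CRFR1-KO 1, 912 genes had a count of 4 and 425 a count of 8, against 356 with 3 and 221 with 7, the pattern of steps of 4 seen in every library.

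The gene models past the adjusted threshold may reflect how reads were divided between gene models that share exons. For Sept2, Zc3h11a and Gm45062, 0 of the 3 summed groups stayed past the threshold, as reads divided differently between gene models that share exons (Sept2, Zc3h11a and Gm45062 models) would give. More widely, of the 10 abundant models at 0 in one library and at 200 or more counts in another, 8 share exons, against 9.05% of the 8839 models that reach 200 counts (odds ratio 40.6, 95% interval 8.07 to 392, two-sided Fisher's exact p = 1.66e-07 across models), and without the called groups 5 of 7 do (odds ratio 25.5, 95% interval 4.17 to 267, p = 0.000103). The explanation of reads shared with another gene model on the same strand (1810007D17Rik) is argued against by the 0 other models that share its exons. For that RNA a genotype effect and a difference between animals in this genomic region both stay open and untested.

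An even loss of all non-acinar tissue would lower the endothelial list as far as the extracellular matrix, fibroblast and macrophage lists. The endothelial median lay 0.921 above that of the matrix list (bootstrap 95% interval over genes 0.654 to 1.28), 0.548 above the fibroblast list (0.34 to 0.897) and 0.803 above the macrophage list (0.579 to 1.14). For these 4 libraries this argues against an even loss. The lists were chosen after they had fallen, and intervals over genes leave out the spread between libraries. The 2 WT libraries alone gave such a gap, with WT 1 above WT 2 by a median of 0.861 in the matrix list and 0.0322 in the endothelial list. Whether the lower lists are the work of WT 1 alone cannot be told apart with 1 WT library left. Without WT 1 the matrix list had a median of -0.305 (interval over genes, which are correlated, -0.524 to -0.104), while setting CRFR1-KO 1 against WT 2 and CRFR1-KO 2 moved it by 0.434. With 4 libraries there are 3 ways to split them 2 and 2, too few for a share under 0.05: the real split called 10 lists, the highest other 15, and 2 of the 3 splits called 10 or more. Setting WT 1 and CRFR1-KO 2 against WT 2 and CRFR1-KO 1 moved the matrix list's median log2 fold change by 0.87, with 11 of 34 members at an unadjusted p under 0.05, against 0.953 and 17 in the real split. A genotype effect on stroma and a difference in how close to the tumour each piece was taken could both give the pattern, and the latter was not tested.

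The lower Sphk1 values are not accounted for by the scaling of the libraries, as the log2 fold change lay at least 3.6 SE below 0 under each of 5 scalings. Less collagen-rich stroma in the CRFR1-KO libraries may contribute. Sphk1 was lower in WT 1 than in WT 2 by a log2 difference of -0.445 where the matrix list was 0.861 higher, which goes against it, but this rests on 2 libraries and cannot be told apart from chance variation. With an adjusted p of 0.682 in edgeR, a difference tied to genotype remains a hypothesis.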
